A study of Mus musculus with 49 samples.

How the data were processed

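Messenger RNA was measured in skin of imiquimod-treated and colon of dextran sulfate sodium-treated mice by poly(A) selection and strand-specific sequencing, per the labels. The authors aligned reads and estimated abundance with RSEM against the mouse genome mm10, without giving versions in their notes, and deposited 1 table per tissue with expected counts per gene and library. Expected counts share reads that fit several genes among them, so values need not be whole numbers: 16.69% of the skin values and 17.33% of the colon values were not whole. There are 23 skin and 26 colon libraries, each named by group and replicate, and every column was matched to a sample of the labels. Of 24475 gene IDs, 24375 were matched to a symbol.

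Library totals were 14.72 M to 19.68 M expected counts in skin and 15.08 M to 18.66 M in colon, and the most abundant gene took 1.56% to 4.78% and 1.38% to 3.91% of them. Counts were rounded and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM factors (0.833 to 1.08 in skin, 0.91 to 1.09 in colon) and quasi-likelihood F tests, with all 4 groups of a tissue in 1 fit. The filter left 15345 genes in skin and 15731 in colon, and the common biological coefficient of variation was 0.201 and 0.29. A gene passed, and is said to have risen, fallen or changed, at a Benjamini-Hochberg adjusted p under 0.05 within its comparison; the SE is the absolute log2 fold change over the square root of F. CPM are counts scaled to the TMM-adjusted library total, given as mean ± SD over libraries. No samples were known to be paired and none was left out of the fits reported first.

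The comparisons in each tissue were disease with PBS against water with PBS, each antibody against PBS under disease, the antibodies against each other, and each antibody group against water. Genes changed by disease and passing in the opposite direction with an antibody were counted, as were genes that both antibodies changed in 1 direction. Because these counts share PBS libraries, they were set against 20 simulations without an antibody effect and against all 20 ways of splitting the 6 PBS libraries 3 and 3. Whether an antibody acted differently in skin and colon was tested as an interaction in a fit of both tissues over 14477 genes.

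The comparisons, the rule for named genes, 37 gene lists and most alternatives were fixed before the data were examined; the exceptions are stated where their values are given. Named genes are the 10 with the largest rise and the 10 with the largest fall in a comparison among those past the threshold with an absolute log2 fold change of at least 1 and a mean log2 CPM of at least 1, up to 4 members of each list, and a fixed set of cytokine genes of the interleukin-36, interleukin-1, interleukin-12 and interleukin-17 families with Tnf, Il6 and Ifng. Predicted or clone-named genes, pseudogenes and sex-linked genes were left out of the largest changes, and the text prints part of the named genes. Lists needed 5 measured members, and scores are mean log2 CPM (prior count 2). Tests used camera of limma 3.58.1 at a preset correlation of 0.01 or an estimated one, and fry. Adjustment covered 144 tests in skin and 136 in colon. With an estimated correlation 0 list calls held in skin (lowest adjusted p 0.469) and 0 in colon (lowest 0.0529). Each camera call thus depends on the preset value, while fry made 33 list calls in skin and 45 in colon. Where a group had 0 counts in every library, the fold is given as a bound against a floor of 3 counts over the group. Genes sharing reads with relatives are marked by values that are not whole.

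Alternatives were DESeq2 1.42.0 size factors in edgeR, no filter for low counts, the DESeq2 Wald test, limma-voom with sample weights, fits of the compared groups alone, leaving out each library in turn, and, for skin, PBS replicates 1 to 3 or 4 to 6 alone. The last follow the sample numbers: IMQ PBS replicates 1 to 3 are numbered with the water controls, replicates 4 to 6 with anti-IL-36R, and the anti-IL-12p40 libraries form a run of their own. Between PBS replicates 4 to 6 and 1 to 3, 0 genes passed by edgeR and 686 had an unadjusted p under 0.05; other tools were not run on this contrast. Each comparison was repeated on 100 splits of its libraries, or on all 84 where fewer exist. The methods were tested on simulated data with the group sizes of the study, where edgeR recovered 90.9% to 100% of genes changed 4-fold and 62.7% to 89.6% of those changed 2-fold. By Xist all libraries were female, so sex cannot show swaps, and no duplicate lay within a group. Plots used Python 3.11.15 and matplotlib 3.10.9.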

Results

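The libraries came from DITRA-like mice, a model of deficiency of the interleukin-36 receptor antagonist (DITRA), a disorder in which the natural inhibitor of interleukin-36 signalling is lost. Skin was inflamed with imiquimod (IMQ), a Toll-like receptor agonist, and colon with dextran sulfate sodium (DSS), a polymer that injures the lining of the large intestine. Treated animals were injected with PBS, with an antibody to the human interleukin-36 receptor (anti-IL-36R) or with an antibody to mouse IL-12p40 (anti-IL-12p40), the subunit that interleukin-12 and interleukin-23 share. The skin table held 23 libraries: 3 from water controls given PBS, 6 from IMQ with PBS, 7 from IMQ with anti-IL-36R and 7 from IMQ with anti-IL-12p40. The colon table held 26 libraries: 5 from water controls given PBS, 6 from DSS with PBS, 8 from DSS with anti-IL-36R and 7 from DSS with anti-IL-12p40. Values below are log2 fold changes ± SE with adjusted p, or CPM as mean ± SD.

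Counts were assigned to the mouse reference, in which the gene of the interleukin-36 receptor is Il1rl2 (Entrez gene ID 107527, chromosome 1, 40324589 to 40367555) and that of its natural antagonist Il1f5 (Entrez gene ID 54450, chromosome 2, 24276954 to 24282432). Skin Il1rl2 stood at 19.2 ± 1.42 CPM (SD, n = 3) in water controls and 21.7 ± 3.82 CPM (SD, n = 6) under IMQ with PBS. Il1f5 was counted in every skin library, at 533 ± 223 CPM (SD, n = 3) in water controls and 483 ± 223 CPM (SD, n = 6) under IMQ with PBS; counts per gene do not show which part of the transcript was read, nor how far mouse Il1rl2 stands for the human receptor that the antibody targets. Neither gene passed the test in skin, with log2 fold change 0.18 ± 0.118, adjusted p = 0.25 for Il1rl2 and log2 fold change -0.14 ± 0.264, adjusted p = 0.702 for Il1f5.

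IMQ with PBS was compared with water controls to find what imiquimod changed in skin. Most transcripts listed for neutrophil chemokines, antimicrobial proteins and stress keratinocyte proteins rose, and most of those for the cornified layer, dendritic cells, T cells and collagens fell. Cxcl2, a chemokine that draws neutrophils (Entrez gene ID 20310, chromosome 5, 90903899 to 90905938), rose from 0.313 ± 0.485 CPM (SD, n = 3) in water controls to 34.1 ± 34.5 CPM (SD, n = 6) under IMQ (log2 fold change 6.66 ± 1.62, adjusted p = 0.00421; 5.86 against PBS replicates 1 to 3 and 7.20 against replicates 4 to 6). Flg2, a filaggrin-like protein of the cornified layer (Entrez gene ID 229574, chromosome 3, 93197273 to 93221377), fell from 1280 ± 783 CPM (SD, n = 3) to 51 ± 36.8 CPM (SD, n = 6) (log2 fold change -4.65 ± 0.572, adjusted p = 4.91e-05; -4.26 against PBS replicates 1 to 3 and -5.15 against replicates 4 to 6). In all, 5046 of 15345 tested genes passed the test, 2377 higher and 2669 lower under IMQ, and 6851 had an unadjusted p under 0.05. The libraries of both groups did not overlap for 4091 genes, against 2.38% of genes by chance for 6 against 3.

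The inflammatory side of the IMQ change was broad. For neutrophil chemokines, 9 members were measured, of which 8 rose and 1 was not called. Here 9 rose when adjusted over the list alone (camera adjusted p = 0.000131, and adjusted p = 0.508 with an estimated correlation), with Cxcl3 at 7.96 ± 1.7, adjusted p = 0.00181. For general inflammatory cytokines, 19 members were measured, of which 12 rose and 7 were not called. Adjusted over the list alone, 13 rose (camera adjusted p = 4.3e-06, and adjusted p = 0.508 with an estimated correlation). Il1b, a central inflammatory cytokine, rose by 3.94 ± 0.785, adjusted p = 0.00116. Of the genes around interleukin-17, Il17f rose from 0.408 ± 0.0768 CPM (SD, n = 3) to 4.53 ± 2.31 CPM (SD, n = 6) (log2 fold change 3.44 ± 0.656, adjusted p = 0.000887), Il22 rose by 3.33 ± 1.2, adjusted p = 0.0375, and Il23a by 2.76 ± 0.81, adjusted p = 0.0132; of 16 alternatives 8 and 3 lost these calls (adjusted p up to 0.122 and 0.0744). Il17a was at 1.66 ± 0.779, adjusted p = 0.102, Il6 at 2.19 ± 0.943, adjusted p = 0.076 and Il12b, which encodes the p40 subunit, at -0.91 ± 0.708, adjusted p = 0.326, so these did not pass. Tnf rose by 1.57 ± 0.491, adjusted p = 0.019, a call lost under 3 of 16 alternatives (up to 0.114). For the IL-12, IL-23 and IL-17 genes together, 16 members were measured, of which 4 rose, 4 fell and 8 were not called. Here 4 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.941, and adjusted p = 0.98 with an estimated correlation). Among the rises of largest size in well-measured genes was that of Fcrl5, an Fc receptor-like gene of lymphoid cells. It had 0 counts in all 3 water libraries and was at least 166-fold higher under IMQ against a floor of 3 counts over that group. The myeloid receptors Cd300e (7.20 ± 0.938) and Fpr1 (6.59 ± 1.37) rose too, as did the chitinase-like gene Chil3 (5.70 ± 1.28), the carboxylate transporter Slc13a3 (5.0 ± 1.06) and the B cell chemokine Cxcl13 (4.58 ± 1.04).

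Most antimicrobial and myeloid genes that passed rose under IMQ. For antimicrobial proteins, 18 members were measured, of which 10 rose, 2 fell and 6 were not called. Here 12 rose and 2 fell when adjusted over the list alone (camera adjusted p = 2.99e-06, and adjusted p = 0.469 with an estimated correlation). S100a9, a subunit of calprotectin, rose from 924 ± 660 CPM (SD, n = 3) to 7250 ± 2100 CPM (SD, n = 6) (log2 fold change 2.97 ± 0.58, adjusted p = 0.00102), Lcn2, an iron-sequestering protein, by 2.75 ± 0.385, and the beta-defensin Defb3 by 4.05 ± 0.786. For neutrophil markers, 16 members were measured, of which 11 rose and 5 were not called. Here 13 rose when adjusted over the list alone (camera adjusted p = 7.73e-06, and adjusted p = 0.508 with an estimated correlation), including Trem1 (4.14 ± 0.964) and Csf3r (2.51 ± 0.522). For monocyte and macrophage markers, 16 members were measured, of which 10 rose and 6 were not called. Here 11 rose when adjusted over the list alone (camera adjusted p = 7.73e-06, and adjusted p = 0.508 with an estimated correlation), including Adgre1 (2.42 ± 0.401) and Itgam (1.98 ± 0.4). For matrix remodelling and repair genes, 19 members were measured, of which 14 rose and 5 were not called. Here 14 rose when adjusted over the list alone (camera adjusted p = 3.68e-06, and adjusted p = 0.508 with an estimated correlation), with the growth factor Hbegf at 2.77 ± 0.546, adjusted p = 0.00109.

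For keratinocyte activation genes, 28 members were measured, of which 25 rose, 1 fell and 2 were not called. Here 27 rose and 1 fell when adjusted over the list alone (camera adjusted p = 4.56e-17, and adjusted p = 0.469 with an estimated correlation). Sprr2e, a small proline-rich protein, rose from 45.6 ± 27.6 CPM (SD, n = 3) to 428 ± 106 CPM (SD, n = 6) (log2 fold change 3.23 ± 0.539, adjusted p = 0.000383), Sprr1a by 1.81 ± 0.304 and the stress keratin Krt17 by 1.16 ± 0.203; their counts were not whole numbers in any library, which marks reads shared with related genes. For cornified barrier genes, 30 members were measured, of which 3 rose, 17 fell and 10 were not called. When adjusted over the list alone, 4 rose and 17 fell (camera adjusted p = 0.000378, and adjusted p = 0.62 with an estimated correlation), with Lce1m at -3.01 ± 0.43, adjusted p = 0.000131. The falls of largest size also took in the keratin Krt77 (-7.26 ± 1.11), the epidermal lipoxygenase Alox12e (-4.54 ± 0.673), the cytochrome Cyp2g1 (-4.01 ± 0.828) and Fcgbp (-3.86 ± 0.542). For skin barrier lipid genes, 25 members were measured, of which 5 rose, 9 fell and 11 were not called. Here 6 rose and 9 fell when adjusted over the list alone (camera adjusted p = 0.334, and adjusted p = 0.86 with an estimated correlation); their median log2 fold change was 0.12 while the test pointed down. Among these, Scd1 fell (-2.15 ± 0.342, adjusted p = 0.000265), as did Elovl6 (-2.33 ± 0.446, adjusted p = 0.000913). Both make fatty acids.

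For dendritic and Langerhans cell markers, 14 members were measured, of which 11 fell and 3 were not called. Here 11 fell when adjusted over the list alone (camera adjusted p = 1.77e-06, and adjusted p = 0.508 with an estimated correlation), with Clec9a at -5.77 ± 0.867, adjusted p = 0.000183, Flt3 at -2.29 ± 0.268 and Cd209a at -4.18 ± 0.782. For T and NK cell markers, 15 members were measured, of which 2 rose, 10 fell and 3 were not called. Here 2 rose and 10 fell when adjusted over the list alone (camera adjusted p = 0.00647, and adjusted p = 0.614 with an estimated correlation), with falls of Foxp3 (-1.98 ± 0.304) and Cd3e (-1.73 ± 0.301) and a rise of the granzyme Gzma (4.07 ± 0.631, adjusted p = 0.000222). For fibroblast matrix genes, 15 members were measured, of which 12 fell and 3 were not called. Here 12 fell when adjusted over the list alone (camera adjusted p = 7.73e-06, and adjusted p = 0.508 with an estimated correlation), with Col1a2 at -1.41 ± 0.273, adjusted p = 0.000961. The adipocyte score was lower too (-0.89, adjusted p = 0.0402), while skeletal (-1.17, 0.0612) and smooth muscle (-0.565, 0.0673) missed the threshold. For hair follicle genes, 17 members were measured, of which 1 rose, 8 fell and 8 were not called. Here 12 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.00198, and adjusted p = 0.614 with an estimated correlation), with Krt28 at -5.43 ± 1.16 and Krt73 at -5.74 ± 1.35. The water controls share a run of sample numbers with IMQ PBS replicates 1 to 3; against those replicates 3817 genes passed, and against replicates 4 to 6 the count was 3419.

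**Figure D1:**
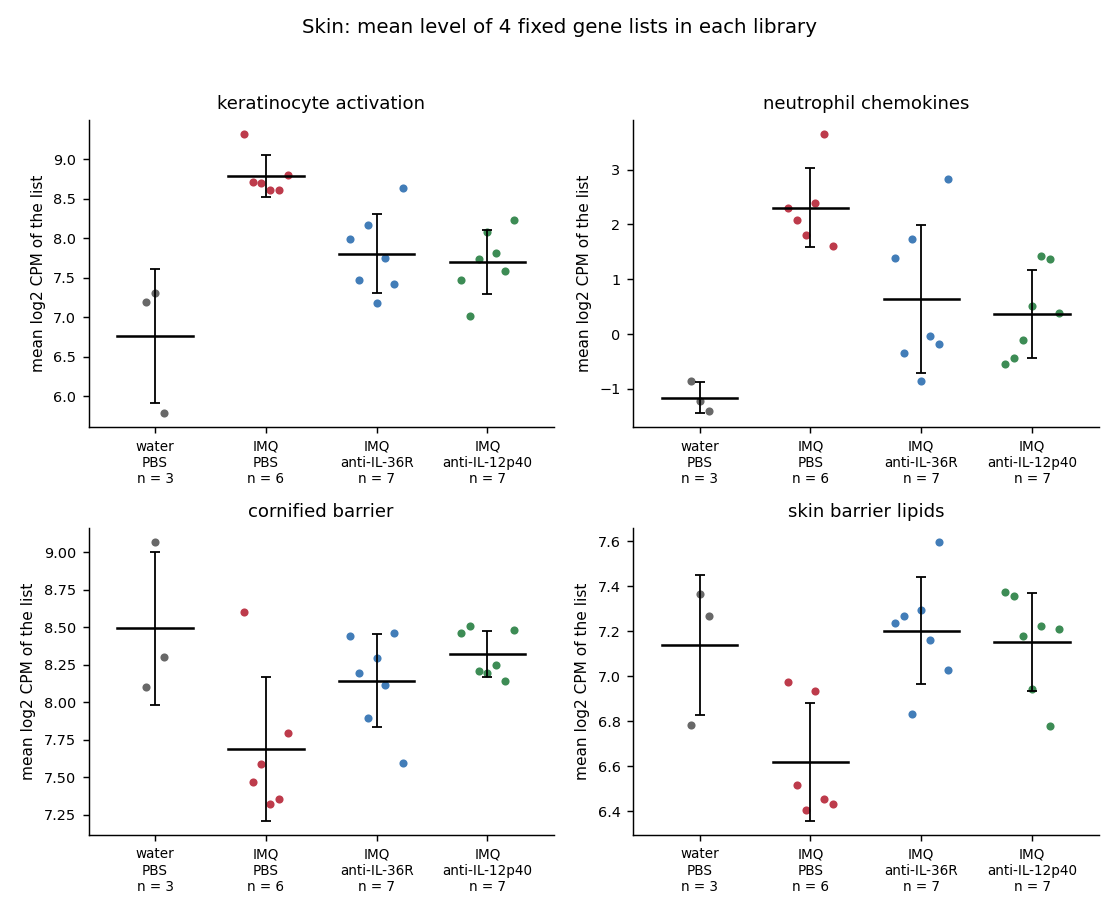
Mean log2 CPM of 4 gene lists (vertical axes) in each skin library (points), for water controls and the 3 IMQ groups; horizontal lines are group means and bars are 1 SD. IMQ PBS replicate 1 stands at 9.32 for keratinocyte activation and 8.6 for the cornified barrier, above the other 5 IMQ PBS libraries on both.

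Anti-IL-36R was compared with PBS under IMQ to find what blocking the interleukin-36 receptor changed in inflamed skin. Flg2 and part of the barrier lipid genes rose, and 14 of 28 keratinocyte activation genes fell. Flg2 rose from 51 ± 36.8 CPM (SD, n = 6) to 429 ± 291 CPM (SD, n = 7) (log2 fold change 3.08 ± 0.49, adjusted p = 0.00241; 2.69 against PBS replicates 1 to 3 and 3.59 against replicates 4 to 6), and Sprr2e fell from 428 ± 106 CPM (SD, n = 6) to 149 ± 113 CPM (SD, n = 7) (log2 fold change -1.52 ± 0.358, adjusted p = 0.0187; -1.70 against PBS replicates 1 to 3 and -1.33 against replicates 4 to 6). In all, 628 of 15345 genes passed, 492 higher and 136 lower with the antibody, and 3286 had an unadjusted p under 0.05. Mouse Il1rl2 was at -0.01 ± 0.0918, adjusted p = 0.975, with 21.6 ± 2.25 CPM (SD, n = 7) under the antibody.

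For keratinocyte activation genes under anti-IL-36R, 28 members were measured, of which 14 fell and 14 were not called. Here 18 fell and 1 rose when adjusted over the list alone (camera adjusted p = 2.79e-16, and adjusted p = 0.469 with an estimated correlation), with falls of Sprr1a (-0.97 ± 0.219, adjusted p = 0.0144; -1.05 against PBS replicates 1 to 3 and -0.90 against replicates 4 to 6) and the late envelope gene Lce3b (-1.75 ± 0.384). For cornified barrier genes, 30 members were measured, of which 3 rose and 27 were not called. Here 7 rose and 2 fell when adjusted over the list alone (camera adjusted p = 4.43e-05, and adjusted p = 0.614 with an estimated correlation), with Lce1m at 1.95 ± 0.371. Krt77 (4.28 ± 0.981), the thioesterase Olah (2.95 ± 0.491) and the channel protein Panx3 (2.74 ± 0.516) were among the rises of largest size. For skin barrier lipid genes, 25 members were measured, of which 9 rose and 16 were not called. Adjusted over the list alone, 9 rose and 1 fell (camera adjusted p = 0.000981, and adjusted p = 0.565 with an estimated correlation), with the wax synthase Awat1 at 2.20 ± 0.392, adjusted p = 0.00418, Elovl3 at 2.24 ± 0.38 and Scd3 at 2.13 ± 0.367. For tight junction genes, 17 members were measured, of which 6 rose and 11 were not called. Here 7 rose when adjusted over the list alone (camera adjusted p = 0.00122, and adjusted p = 0.508 with an estimated correlation), with Epcam at 0.75 ± 0.177 and Cldn3 at 3.45 ± 0.791, the latter with means under 1 CPM in both groups. For dendritic cell markers, 14 members were measured, of which 3 rose and 11 were not called. Here 3 rose when adjusted over the list alone (camera adjusted p = 0.000218, and adjusted p = 0.508 with an estimated correlation), with Flt3 at 1.04 ± 0.231 and Clec9a at 3.83 ± 0.91.

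For neutrophil chemokines under anti-IL-36R, 9 members were measured, of which 1 fell and 8 were not called. Here 4 fell when adjusted over the list alone (camera adjusted p = 0.00125, and adjusted p = 0.508 with an estimated correlation); Cxcl3 fell (-2.63 ± 0.729, adjusted p = 0.0433), while Cxcl2 stood at 5.28 ± 7.9 CPM (SD, n = 7) with -2.67 ± 0.819, adjusted p = 0.0662. For antimicrobial proteins, 18 members were measured, of which 1 rose, 2 fell and 15 were not called. Here 5 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.0291, and adjusted p = 0.614 with an estimated correlation), with a fall of Defb3 (-2.17 ± 0.498) and a rise of another beta-defensin, Defb6 (1.22 ± 0.237). Among the falls of largest size were the S100 protein S100a7a (-2.07 ± 0.507), the phospholipase Pla2g4d (-2.0 ± 0.379) and Vsig8 (-2.46 ± 0.677), and Il18 rose by 0.97 ± 0.201. Il1b was at -1.56 ± 0.487, adjusted p = 0.0712, Il17f at -0.60 ± 0.392, adjusted p = 0.391, Il17a at -0.45 ± 0.529, adjusted p = 0.662, Il22 at -1.11 ± 0.704, adjusted p = 0.376, Il23a at -0.87 ± 0.512, adjusted p = 0.336 and Tnf at -0.42 ± 0.348, adjusted p = 0.508, none past the threshold.

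The number of genes changed by anti-IL-36R in skin moved with single libraries. Leaving out 1 library gave 298 to 1186 genes (without anti-IL-36R replicates 6 and 7), and against PBS replicates 1 to 3 alone or 4 to 6 alone the counts were 106 and 50. DESeq2 called 1112 genes and limma-voom 2750, and of the 22 named genes that passed, 0 did so under every alternative; of 20 alternatives, Vsig8 lost its call under 14 and Cxcl3 under 13.

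Anti-IL-12p40 was compared with PBS under IMQ to find what blocking the shared subunit of interleukin-12 and interleukin-23 changed in skin. Il17f, Il17a, Il22 and part of the neutrophil chemokine and keratinocyte activation genes fell, and part of the cornified barrier and T cell genes rose. Il17f (Entrez gene ID 257630, chromosome 1, 20777146 to 20785274) fell from 4.53 ± 2.31 CPM (SD, n = 6) to 0.462 ± 0.255 CPM (SD, n = 7) (log2 fold change -3.25 ± 0.456, adjusted p = 0.00065; -3.44 against PBS replicates 1 to 3 and -3.06 against replicates 4 to 6). Flg2 rose from 51 ± 36.8 CPM (SD, n = 6) to 652 ± 191 CPM (SD, n = 7) (log2 fold change 3.68 ± 0.507, adjusted p = 0.000642; 3.29 against PBS replicates 1 to 3 and 4.18 against replicates 4 to 6), and Cxcl2 fell from 34.1 ± 34.5 CPM (SD, n = 6) to 1.58 ± 1.72 CPM (SD, n = 7) (log2 fold change -4.45 ± 0.918, adjusted p = 0.00601; -3.62 against PBS replicates 1 to 3 and -4.98 against replicates 4 to 6). In all, 1338 of 15345 genes passed, 807 higher and 531 lower with the antibody, and 3871 had an unadjusted p under 0.05.

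Il17a (-2.89 ± 0.657, adjusted p = 0.00952) and Il22 (-5.95 ± 1.15, adjusted p = 0.00434) fell under anti-IL-12p40, both from levels near 1 CPM. Il12b was at 1.06 ± 0.573, adjusted p = 0.254, Il23a at -0.95 ± 0.513, adjusted p = 0.251 and Il1rl2 at -0.01 ± 0.0918, adjusted p = 0.97, so none of these passed. For the IL-12, IL-23 and IL-17 genes together, 16 members were measured, of which 3 rose, 3 fell and 10 were not called. Here 3 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.629, and adjusted p = 0.866 with an estimated correlation); their median log2 fold change was 0.05 while the test pointed down. For inflammatory cytokines, 19 members were measured, of which 8 fell and 11 were not called. Here 9 fell when adjusted over the list alone (camera adjusted p = 1.57e-05, and adjusted p = 0.508 with an estimated correlation), with falls of Il19 (-2.72 ± 0.644) and the prostaglandin synthase Ptgs2 (-2.61 ± 0.653). For neutrophil chemokines, 9 members were measured, of which 4 fell and 5 were not called. When adjusted over the list alone, 4 fell (camera adjusted p = 0.000332, and adjusted p = 0.508 with an estimated correlation), with Cxcl3 at -4.75 ± 0.853. Il1b fell (-2.21 ± 0.499, adjusted p = 0.00934). For antimicrobial proteins, 18 members were measured, of which 2 rose, 5 fell and 11 were not called. Here 2 rose and 8 fell when adjusted over the list alone (camera adjusted p = 0.00125, and adjusted p = 0.508 with an estimated correlation); S100a9 fell to 1940 ± 854 CPM (SD, n = 7) (log2 fold change -1.91 ± 0.396, adjusted p = 0.00602), and Defb3 fell (-2.43 ± 0.504). For neutrophil markers, 16 members were measured, of which 2 fell and 14 were not called. Here 2 fell when adjusted over the list alone (camera adjusted p = 0.000584, and adjusted p = 0.508 with an estimated correlation), with Trem1 at -1.97 ± 0.575, a call lost under 11 of 20 alternatives (adjusted p up to 0.217).

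For keratinocyte activation genes under anti-IL-12p40, 28 members were measured, of which 1 rose, 15 fell and 12 were not called. Here 20 fell and 1 rose when adjusted over the list alone (camera adjusted p = 8.9e-18, and adjusted p = 0.469 with an estimated correlation), with falls of Sprr2b (-2.67 ± 0.377) and Sprr2e, the latter to 98.8 ± 26.9 CPM (SD, n = 7) (log2 fold change -2.11 ± 0.364, adjusted p = 0.00222). For cornified barrier genes, 30 members were measured, of which 10 rose and 20 were not called. Here 18 rose and 1 fell when adjusted over the list alone (camera adjusted p = 6.99e-07, and adjusted p = 0.516 with an estimated correlation), with Hrnr at 1.20 ± 0.295. Krt77 (5.17 ± 0.996), Olah (3.41 ± 0.491) and Fcgbp (3.0 ± 0.477) were among the rises of largest size. For skin barrier lipid genes, 25 members were measured, of which 9 rose and 16 were not called. Here 9 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.0195, and adjusted p = 0.642 with an estimated correlation), with Scd1 at 1.58 ± 0.29 and Elovl3 at 2.07 ± 0.377. For tight junction genes, 17 members were measured, of which 6 rose and 11 were not called. Here 6 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0209, and adjusted p = 0.605 with an estimated correlation), with Cldn3 at 3.74 ± 0.775. For T and NK cell markers, 15 members were measured, of which 8 rose and 7 were not called. Here 12 rose when adjusted over the list alone (camera adjusted p = 1.14e-07, and adjusted p = 0.469 with an estimated correlation), with rises of Foxp3 (1.59 ± 0.259, adjusted p = 0.00164), Cd2 (1.43 ± 0.239) and Ctla4 (1.41 ± 0.305). For dendritic cell markers, 14 members were measured, of which 4 rose and 10 were not called. Adjusted over the list alone, 5 rose (camera adjusted p = 0.00117, and adjusted p = 0.508 with an estimated correlation), with Flt3 at 1.17 ± 0.231 and Clec9a at 3.47 ± 0.937. For matrix remodelling and repair genes, 19 members were measured, of which 5 fell and 14 were not called. Here 9 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.000544, and adjusted p = 0.508 with an estimated correlation), with falls of the growth factors Hbegf (-1.60 ± 0.372) and Tgfa (-1.08 ± 0.201). For hair follicle genes, 17 members were measured, of which 4 rose, 1 fell and 12 were not called. Here 10 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0384, and adjusted p = 0.734 with an estimated correlation), with Krt28 at 3.57 ± 1.05 and Krt73 at 4.36 ± 1.23, calls that 13 and 10 of 20 alternatives lost (1.32 and 1.58 without anti-IL-12p40 replicate 2). The falls of largest size included Uox, which encodes urate oxidase (-3.20 ± 0.531), and the lipoxygenase Alox8 (-2.56 ± 0.488).

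The rise with the lowest adjusted p under anti-IL-12p40 was that of Igf2bp3, an RNA-binding protein known from embryonic tissue (Entrez gene ID 140488, chromosome 6, 49085218 to 49215469). It went from 0.906 ± 0.612 CPM (SD, n = 6) to 55.4 ± 11 CPM (SD, n = 7) (log2 fold change 5.88 ± 0.316, adjusted p = 9.79e-11). The anti-IL-12p40 libraries form a run of sample numbers of their own, so no value within a run can be had for them. The count of 1338 became 429 against PBS replicates 1 to 3 and 193 against replicates 4 to 6, 737 to 1799 when 1 library was left out, and 2677 by limma-voom.

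**Figure D2:**
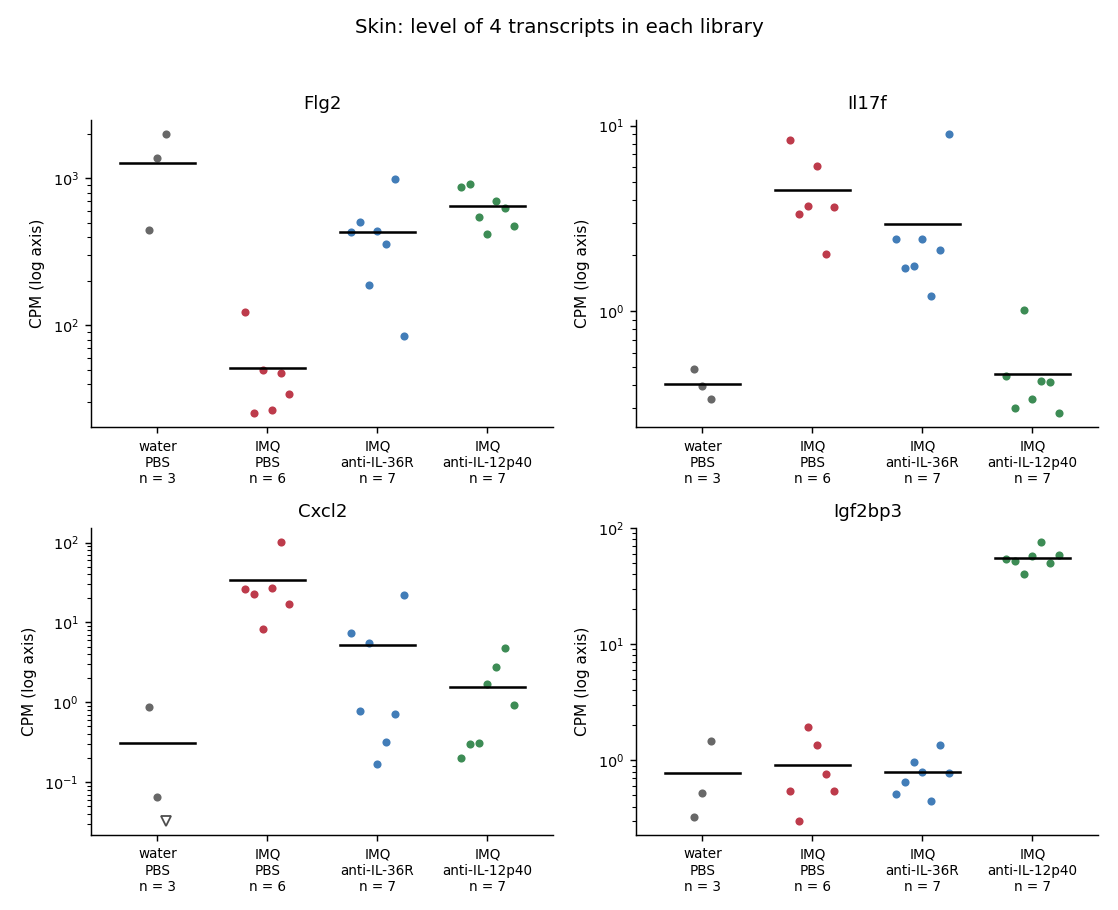
CPM on a log axis (vertical) of Flg2, Il17f, Cxcl2 and Igf2bp3 in each skin library (points), by group; lines are group means and the open triangle is a library with 0 counts, drawn just below the lowest value above 0. Igf2bp3 lies between 40.2 and 76.2 CPM in the 7 anti-IL-12p40 libraries, and anti-IL-36R replicate 7 stands apart at 9.02 CPM of Il17f.

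The antibodies were compared directly in skin. Igf2bp3 was lower with anti-IL-36R (-6.12 ± 0.3, adjusted p = 1.53e-11) and Il17f was higher (2.65 ± 0.448, adjusted p = 0.0182; 2.96 ± 2.71 CPM (SD, n = 7) against 0.462 ± 0.255 CPM (SD, n = 7)). Of 19 alternatives 8 lost the Il17f call (adjusted p up to 0.0828), and anti-IL-36R replicate 7 stood apart at 9.02 CPM. Only 7 of 15345 genes passed, 2 higher and 5 lower with anti-IL-36R, and 806 had an unadjusted p under 0.05. The other 5, named after their values were seen, were 4930463O16Rik, Krt13 (-2.16), Gm5779 (-1.38) and Gcn1 (-0.43), all lower, and 5830411N06Rik, which was higher. Camera called 11 of 36 lists, 6 higher and 5 lower with anti-IL-36R, and fry called 0. Of the list scores, only that of erythroid genes passed, lower (difference -1.52, adjusted p = 0.0443), with 0 of its 6 genes called. Il17a was at 2.44 ± 0.655, adjusted p = 0.454, Il22 at 4.83 ± 1.22, adjusted p = 0.404, Il1b at 0.65 ± 0.479, adjusted p = 1 and Il12b at -1.08 ± 0.542, adjusted p = 0.971. DESeq2 called 22 genes, 4 passed in a fit of these groups alone, and 3 to 8 without 1 library.

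Part of the genes that IMQ changed passed in the opposite direction with each antibody, and 0 passed in the same direction. Of the 5046 genes that IMQ changed, 508 passed in the opposite direction with anti-IL-36R, 98 that rose and then fell and 410 that fell and then rose; 21.07 and 85.57 were expected of unrelated lists. Leaving out 1 library moved these counts to between 29 and 357 and between 218 and 616. With anti-IL-12p40 it was 1153, 462 that fell after rising and 691 that rose after falling, against 82.25 and 140.4 for unrelated lists (235 to 752 and 407 to 738 without 1 library). Both comparisons hold the IMQ PBS libraries, which alone gives opposite signs. For anti-IL-36R and anti-IL-12p40, 87.97% and 94.61% of the 5046 genes had opposite signs, against 59.79% and 59.93% in simulations without effect. The simulations spanned only 58.56% to 61.19%, a limit, since chance can shift many genes together. With PBS libraries split to share none, medians were 81.69% and 89.16% (lowest 72.67% and 82.39%). The median counts were 49.5 (0 to 232) and 269 (118 to 463). Anti-IL-36R and anti-IL-12p40 shared 493 genes changed in the same direction, 393 higher and 100 lower, against 25.87 and 4.706 for unrelated lists. With split PBS libraries they shared a median of 25.5 genes (0 to 52), against 0.723 higher and 0.0759 lower for unrelated lists. The covariance of their log2 fold changes was 0.186 (simulated 0.029).

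Genes that differed from water controls were counted whether or not IMQ alone had changed them. With anti-IL-36R under IMQ, 2003 genes passed against water, 910 higher and 1093 lower, and with anti-IL-12p40 the count was 729, 369 higher and 360 lower. These counts depend on the 3 water libraries. The first was 698 without water replicate 1, 1248 without replicate 3 and 1174 in a fit of those groups alone. The second was 118, 433 and 467 without water replicates 1, 2 and 3, up to 1117 without 1 antibody library, 470 in a fit of those groups alone and 1305 by DESeq2.

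DSS with PBS was compared with water controls to find what dextran sulfate sodium changed in colon. Most neutrophil, chemokine, interferon and plasma cell genes rose, and part of the absorptive and detoxifying epithelial genes fell. S100a8, the partner of S100a9 in calprotectin (Entrez gene ID 20201, chromosome 3, 90669071 to 90670034), rose from 0.114 ± 0.106 CPM (SD, n = 5) in water controls to 476 ± 464 CPM (SD, n = 6) under DSS (log2 fold change 12 ± 1.39, adjusted p = 1.43e-06). Lcn2 rose from 1.13 ± 0.51 CPM (SD, n = 5) to 227 ± 205 CPM (SD, n = 6) (log2 fold change 7.67 ± 0.808, adjusted p = 9.94e-07), and Il1b (Entrez gene ID 16176, chromosome 2, 129364569 to 129371164) from 1.01 ± 0.482 CPM (SD, n = 5) to 316 ± 374 CPM (SD, n = 6) (log2 fold change 8.31 ± 1.01, adjusted p = 2.16e-06). In all, 5065 of 15731 tested genes passed, 2762 higher and 2303 lower, and 6667 had an unadjusted p under 0.05. The libraries of both groups did not overlap for 2058 genes, against 0.433% by chance for 6 against 5.

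For neutrophil markers under DSS, 18 members were measured, of which 17 rose and 1 was not called. Here 17 rose when adjusted over the list alone (camera adjusted p = 2.48e-14, and adjusted p = 0.0743 with an estimated correlation), with Clec4e at 11.23 ± 1.36. For neutrophil chemokines, 9 members were measured, of which 9 rose. Here 9 rose when adjusted over the list alone (camera adjusted p = 5.47e-09, and adjusted p = 0.124 with an estimated correlation); Cxcl2 rose from 0.0445 ± 0.0733 CPM (SD, n = 5) to 47.1 ± 63.2 CPM (SD, n = 6) (log2 fold change 9.73 ± 1.4, adjusted p = 1.38e-05), Cxcl1 by 6.51 ± 0.754 and Ccl3 by 8.94 ± 1.16. For antimicrobial proteins, 18 members were measured, of which 13 rose and 5 were not called. Here 13 rose and 1 fell when adjusted over the list alone (camera adjusted p = 5.33e-10, and adjusted p = 0.0529 with an estimated correlation), with S100a9 at 12.43 ± 1.35. Further rises of large size were those of the collagenase Mmp8 (11.32 ± 1.5), Chil3 (11.06 ± 1.78), lactoferrin Ltf (9.21 ± 1.66) and the acute-phase gene Saa3 (9.25 ± 1.11). For inflammatory cytokines, 14 members were measured, of which 13 rose and 1 was not called. Here 13 rose when adjusted over the list alone (camera adjusted p = 9.25e-13, and adjusted p = 0.0804 with an estimated correlation), with Osm at 6.72 ± 0.786, Il11 at 6.46 ± 0.789, Il6 at 7.46 ± 0.993 and Tnf at 3.55 ± 0.513. For matrix remodelling and repair genes, 20 members were measured, of which 17 rose and 3 were not called. When adjusted over the list alone, 18 rose (camera adjusted p = 5.09e-13, and adjusted p = 0.0622 with an estimated correlation), with the stromelysins Mmp3 (7.28 ± 0.7) and Mmp10 (7.09 ± 0.796) and their inhibitor Timp1 (4.75 ± 0.575).

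For the IL-12, IL-23 and IL-17 genes under DSS, 18 members were measured, of which 13 rose, 3 fell and 2 were not called. Here 13 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.00039, and adjusted p = 0.27 with an estimated correlation), with Il17a at 6.89 ± 1.2, adjusted p = 0.00012, Il17f at 4.20 ± 0.892, Il22 at 4.43 ± 1.27, adjusted p = 0.00955, Ifng at 6.11 ± 1.67, adjusted p = 0.007, Il12b at 3.82 ± 0.681 and Il12a at 1.58 ± 0.512, adjusted p = 0.0201. By limma-voom Ifng (2.55; adjusted p 0.00161 to 0.168 over the alternatives) and Il12a (0.62; 0.00368 to 0.204) lost their calls, the latter under 6 of 18 alternatives. Il1rl2 rose from 0.396 ± 0.238 CPM (SD, n = 5) to 1.78 ± 1.22 CPM (SD, n = 6) (log2 fold change 2.16 ± 0.509, adjusted p = 0.00232). For interferon gamma response genes, 25 members were measured, of which 25 rose. Here 25 rose when adjusted over the list alone (camera adjusted p = 1.46e-10, and adjusted p = 0.324 with an estimated correlation), with Cxcl10 at 4.94 ± 0.981. For T and NK cell markers, 16 members were measured, of which 15 rose and 1 was not called. Here 15 rose when adjusted over the list alone (camera adjusted p = 1.88e-10, and adjusted p = 0.229 with an estimated correlation), with Foxp3 at 3.62 ± 0.457. For B and plasma cell markers, 12 members were measured, of which 12 rose. Here 12 rose when adjusted over the list alone (camera adjusted p = 1.65e-07, and adjusted p = 0.27 with an estimated correlation), with Mzb1 at 3.72 ± 0.551. For monocyte and macrophage markers, 16 members were measured, of which 14 rose and 2 were not called. Here 14 rose when adjusted over the list alone (camera adjusted p = 6.61e-13, and adjusted p = 0.114 with an estimated correlation), with the Fc receptor Fcgr1 at 3.77 ± 0.442. For endothelial markers, 12 members were measured, of which 9 rose and 3 were not called. Here 9 rose when adjusted over the list alone (camera adjusted p = 1.72e-07, and adjusted p = 0.236 with an estimated correlation), with the leukocyte adhesion molecule Sele at 7.11 ± 0.952.

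For absorptive colonocyte genes under DSS, 23 members were measured, of which 12 fell and 11 were not called. Here 14 fell when adjusted over the list alone (camera adjusted p = 1.65e-05, and adjusted p = 0.33 with an estimated correlation), with falls of Slc37a2 (-3.59 ± 0.792) and the carbonic anhydrase Car2 (-1.93 ± 0.442, adjusted p = 0.0018). For xenobiotic metabolism genes, 17 members were measured, of which 14 fell and 3 were not called. Adjusted over the list alone, 14 fell (camera adjusted p = 1.03e-06, and adjusted p = 0.252 with an estimated correlation), with the drug efflux pump Abcb1a at -1.76 ± 0.314, adjusted p = 0.000159 and Aldh1a1 at -2.48 ± 0.47. For tight junction genes, 19 members were measured, of which 5 fell and 14 were not called. Here 7 fell when adjusted over the list alone (camera adjusted p = 0.00329, and adjusted p = 0.467 with an estimated correlation), with occludin Ocln at -1.02 ± 0.203. For smooth muscle genes, 12 members were measured, of which 6 fell and 6 were not called. Here 9 fell when adjusted over the list alone (camera adjusted p = 0.000323, and adjusted p = 0.367 with an estimated correlation), with Myh11 at -0.91 ± 0.262, adjusted p = 0.0099. Syncollin Sycn (-2.93 ± 0.529) and the manganese transporter Slc30a10 (-4.06 ± 0.973) were among the falls of largest size. The falls of Itln1 and Ang4 rested on 2 water libraries: Itln1 stood at 744 CPM in water replicate 4 and 16.7 CPM in replicate 5, with at most 1.05 CPM in the other 3, and Ang4 at 459 and 103 CPM with at most 3.32.

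Squamous keratins were high in 1 DSS library. Krt5 (Entrez gene ID 110308, chromosome 15, 101707069 to 101712905) stood at 1500 CPM in DSS PBS replicate 6 and between 0.191 and 11.1 CPM in the other 5, against 0.337 ± 0.178 CPM (SD, n = 5) in water controls (log2 fold change 9.55 ± 2.07, adjusted p = 0.00115). Krt14 was at 1070 CPM there (6.81 ± 1.75, adjusted p = 0.00474). For basal epidermis markers, 7 members were measured, of which 3 rose and 4 were not called. Here 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.575, and adjusted p = 0.771 with an estimated correlation). Without that library and 4 antibody libraries with liver or pancreas transcripts, Krt5 was at 3.01 (adjusted p = 0.0284) and Krt14 at 1.28 (adjusted p = 0.342), and 3814 genes passed under DSS.

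**Figure D3:**
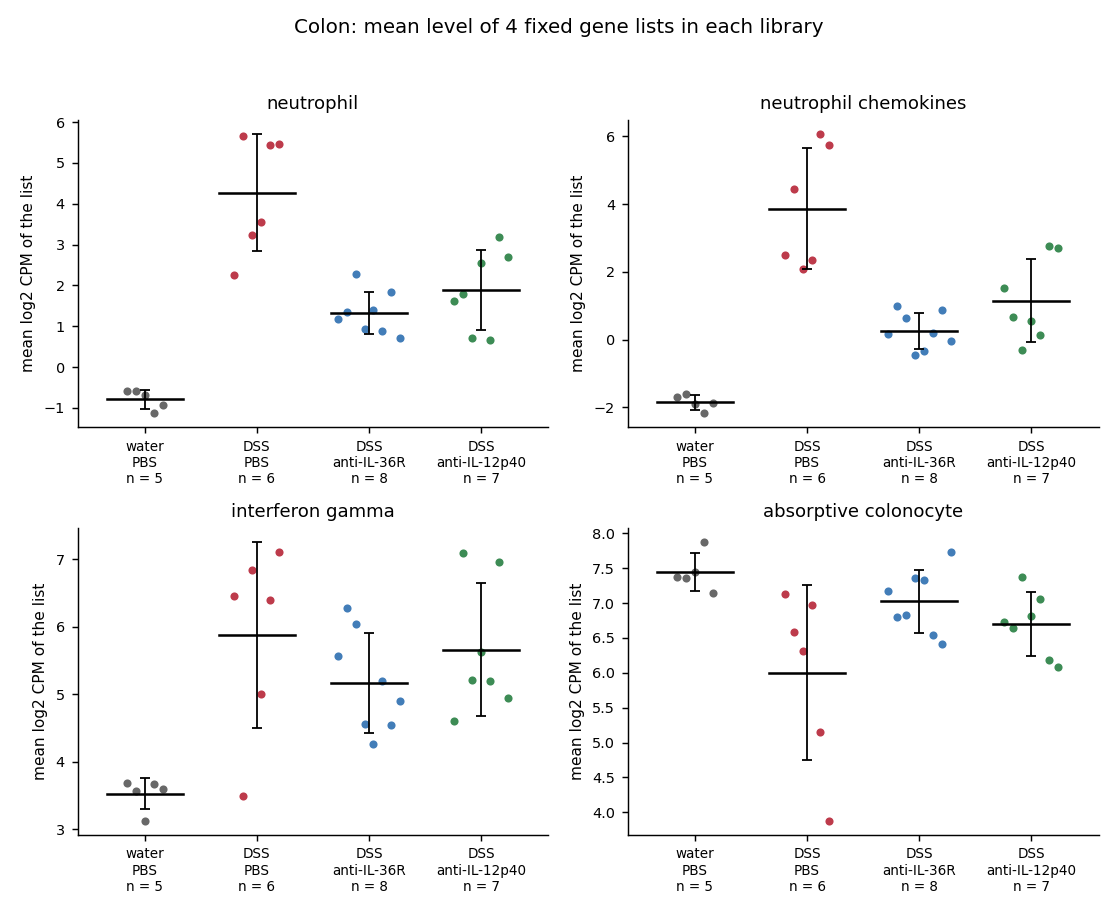
Mean log2 CPM of 4 gene lists (vertical axes) in each colon library (points), for water controls and the 3 DSS groups; horizontal lines are group means and bars are 1 SD. For interferon gamma response genes water replicate 3 stands at 3.12, below the 3.57 to 3.68 of the other 4 water libraries.

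Anti-IL-36R was compared with PBS under DSS to find what blocking the interleukin-36 receptor changed in inflamed colon. Most neutrophil genes and their chemokines and part of the inflammatory cytokine and matrix remodelling genes fell. S100a8 fell from 476 ± 464 CPM (SD, n = 6) to 14.7 ± 9.18 CPM (SD, n = 8) (log2 fold change -5.01 ± 0.743, adjusted p = 0.00027), Lcn2 from 227 ± 205 CPM (SD, n = 6) to 8.84 ± 5.42 CPM (SD, n = 8) (log2 fold change -4.68 ± 0.551, adjusted p = 0.000136) and Il1b from 316 ± 374 CPM (SD, n = 6) to 18.4 ± 11.7 CPM (SD, n = 8) (log2 fold change -4.11 ± 0.647, adjusted p = 0.000439). In all, 1024 of 15731 genes passed, 178 higher and 846 lower with the antibody, and 3637 had an unadjusted p under 0.05.

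For neutrophil markers under anti-IL-36R, 18 members were measured, of which 14 fell and 4 were not called. Here 16 fell when adjusted over the list alone (camera adjusted p = 1.46e-18, and adjusted p = 0.0529 with an estimated correlation), with falls of Mmp8 (-5.77 ± 0.797) and the resistin-like gene Retnlg (-5.04 ± 0.725). For neutrophil chemokines, 9 members were measured, of which 9 fell. Here 9 fell when adjusted over the list alone (camera adjusted p = 1e-13, and adjusted p = 0.0529 with an estimated correlation), with Csf3, the granulocyte growth factor, at -6.51 ± 0.843 and Cxcl3 at -6.08 ± 0.895. For inflammatory cytokines, 14 members were measured, of which 9 fell and 5 were not called. Here 12 fell when adjusted over the list alone (camera adjusted p = 1.36e-15, and adjusted p = 0.0541 with an estimated correlation), with Il6 at -4.51 ± 0.635, Il11 at -4.16 ± 0.551 and Osm at -4.03 ± 0.529. For interleukin-1 family genes, 12 members were measured, of which 7 fell and 5 were not called. When adjusted over the list alone, 7 fell (camera adjusted p = 1.72e-07, and adjusted p = 0.0529 with an estimated correlation). For antimicrobial proteins, 18 members were measured, of which 8 fell and 10 were not called. Here 11 fell when adjusted over the list alone (camera adjusted p = 6.74e-07, and adjusted p = 0.0716 with an estimated correlation), with S100a9 at -4.91 ± 0.719. For matrix remodelling and repair genes, 20 members were measured, of which 12 fell and 8 were not called. Here 15 fell and 1 rose when adjusted over the list alone (camera adjusted p = 8.63e-14, and adjusted p = 0.0541 with an estimated correlation), with Mmp3 at -3.38 ± 0.464. The myeloid genes Chil3 (-6.08 ± 1) and Arg1 (-5.17 ± 1.01) were among the falls of largest size. For endothelial markers, 12 members were measured, of which 3 fell and 9 were not called. Here 9 fell when adjusted over the list alone (camera adjusted p = 2.42e-06, and adjusted p = 0.276 with an estimated correlation), with falls of Sele (-3.23 ± 0.578) and Selp (-2.86 ± 0.474).

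Il17a (-2.83 ± 0.667, adjusted p = 0.0103), Il17f (-2.49 ± 0.634, adjusted p = 0.0178) and Tnf (-1.27 ± 0.387, adjusted p = 0.049) fell with anti-IL-36R in colon. Il22 was at -1.74 ± 0.797, adjusted p = 0.192, Ifng at -2.99 ± 1.02, adjusted p = 0.0749, Il12b at -1.22 ± 0.47, adjusted p = 0.118 and Il1rl2 at -1.01 ± 0.407, adjusted p = 0.138, none past the threshold. Mzb1 (-1.52 ± 0.422) and Fcgr1 (-1.27 ± 0.33) fell. Rises were fewer. For absorptive colonocyte genes, 23 members were measured, of which 0 passed the test. Here 0 passed when adjusted over the list alone (camera adjusted p = 1.16e-06, and adjusted p = 0.298 with an estimated correlation), and Slc37a2 was at 2.02 ± 0.704, adjusted p = 0.0829. For xenobiotic metabolism genes, 17 members were measured, of which 2 rose and 15 were not called. Here 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.13e-05, and adjusted p = 0.293 with an estimated correlation), with Abcb1a at 1.06 ± 0.284, adjusted p = 0.0231. For smooth muscle genes, 12 members were measured, of which 1 rose and 11 were not called. Here 7 rose when adjusted over the list alone (camera adjusted p = 1.59e-06, and adjusted p = 0.27 with an estimated correlation), the riser being Synm (0.83 ± 0.209). For tight junction genes, 19 members were measured, of which 1 rose and 18 were not called. Here 0 passed when adjusted over the list alone (camera adjusted p = 7.07e-06, and adjusted p = 0.279 with an estimated correlation), Marveld3 being at 0.54 ± 0.167, adjusted p = 0.0498. The rises of largest size included Aadac (1.80 ± 0.502), Tppp (1.16 ± 0.273) and the gasdermin Gsdmc4 (1.14 ± 0.311).

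Krt5 (-8.45 ± 1.55, adjusted p = 0.00137) and Krt14 (-5.95 ± 1.35, adjusted p = 0.00795) fell with anti-IL-36R, which rested on DSS PBS replicate 6: without that library and the 4 with liver or pancreas transcripts they were at -1.90 (adjusted p = 0.341) and -0.31 (adjusted p = 0.916). Without those 5 libraries 275 genes passed, 15 higher and 260 lower, and S100a8 was at -5.01 (adjusted p = 0.00539), Lcn2 at -4.81 (adjusted p = 0.00344) and Il1b at -3.98 (adjusted p = 0.00879). The calls of Il17f (-2.26 (adjusted p = 0.159)), Tnf (-1.18 (adjusted p = 0.293)), Arg1 (-3.03 (adjusted p = 0.1)), Mzb1, Fcgr1, Synm, Marveld3, Abcb1a, Aadac, Tppp and Gsdmc4 were lost without them, and so was that of Il17a without water replicate 4 as well (-2.57 (adjusted p = 0.163)). Fewer libraries give less power: without the 5 alone Mzb1 and Fcgr1 were at -1.17 and -1.08, and the last 6 at 0.40 (Marveld3) to 1.68 (Aadac). Of the inflammatory cytokine, matrix remodelling and interleukin-1 family genes, 7 of 14, 10 of 20 and 4 of 12 fell without them. Over 21 alternatives the calls of Tnf and Marveld3 were each lost under 14. The count was 436, 584 and 1768 without DSS PBS replicates 6, 5 and 1, 403 in a fit of these groups alone, 453 by limma-voom and 1558 by DESeq2.

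Anti-IL-12p40 was compared with PBS under DSS to find what blocking IL-12p40 changed in colon. The neutrophil chemokines and part of the neutrophil, antimicrobial and matrix remodelling genes fell. S100a8 fell from 476 ± 464 CPM (SD, n = 6) to 30.3 ± 26.7 CPM (SD, n = 7) (log2 fold change -3.98 ± 0.748, adjusted p = 0.015), Lcn2 to 18.3 ± 10.1 CPM (SD, n = 7) (log2 fold change -3.63 ± 0.553, adjusted p = 0.0118) and Il1b to 45.5 ± 42.7 CPM (SD, n = 7) (log2 fold change -2.80 ± 0.645, adjusted p = 0.0357). In all, 157 of 15731 genes passed, 2 higher and 155 lower with the antibody, and 1892 had an unadjusted p under 0.05.

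For neutrophil markers under anti-IL-12p40, 18 members were measured, of which 11 fell and 7 were not called. Adjusted over the list alone, 15 fell (camera adjusted p = 1.17e-20, and adjusted p = 0.0529 with an estimated correlation), with Mmp8 at -4.65 ± 0.789 and Retnlg at -4.14 ± 0.73. For neutrophil chemokines, 9 members were measured, of which 9 fell. Here 9 fell when adjusted over the list alone (camera adjusted p = 1.92e-13, and adjusted p = 0.0529 with an estimated correlation), with Csf3 at -3.83 ± 0.735 and Cxcl3 at -4.14 ± 0.832. For antimicrobial proteins, 18 members were measured, of which 7 fell and 11 were not called. Here 7 fell when adjusted over the list alone (camera adjusted p = 7.89e-08, and adjusted p = 0.0529 with an estimated correlation), with S100a9 at -3.75 ± 0.721 and the protease inhibitor Slpi at -1.93 ± 0.383. For matrix remodelling and repair genes, 20 members were measured, of which 9 fell and 11 were not called. Here 14 fell when adjusted over the list alone (camera adjusted p = 8.55e-16, and adjusted p = 0.0529 with an estimated correlation), with Mmp3 at -2.38 ± 0.469 and Il11 at -3.07 ± 0.548. For inflammatory cytokines, 14 members were measured, of which 5 fell and 9 were not called. Here 9 fell when adjusted over the list alone (camera adjusted p = 9.25e-13, and adjusted p = 0.0743 with an estimated correlation), with Il6 at -3.32 ± 0.621. Falls of large size were those of Chil3 (-4.99 ± 0.996), Arg1 (-4.13 ± 1) and Ifitm6 (-3.91 ± 0.669), and Selp fell (-2.05 ± 0.483). Il17a was at -2.57 ± 0.684, adjusted p = 0.0673, Il17f at -1.40 ± 0.613, adjusted p = 0.35, Il22 at 0.46 ± 0.729, adjusted p = 0.844, Ifng at -2.02 ± 0.997, adjusted p = 0.422, Tnf at -0.83 ± 0.398, adjusted p = 0.405, Il12b at -0.98 ± 0.482, adjusted p = 0.42, Abcb1a at 0.60 ± 0.288, adjusted p = 0.409 and Il1rl2 at -1.0 ± 0.422, adjusted p = 0.323, none past the threshold.

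All gene calls of this comparison were lost without the 5 libraries with squamous, liver or pancreas transcripts, where 0 genes passed by edgeR and 908 had an unadjusted p under 0.05; S100a8 was then at -3.51 (adjusted p = 0.354) and Lcn2 at -3.35 (adjusted p = 0.354). By camera with the preset correlation 12 list calls stood there against 17 with all libraries, among them neutrophil markers (median -2.32). Krt5 (-7.59 ± 1.55, adjusted p = 0.0196) and Krt13 (-4.83 ± 1.15, adjusted p = 0.0388) fell, which rested on DSS PBS replicate 6, and stood at -0.71 (adjusted p = 0.978) and 0.30 (adjusted p = 0.991) without those libraries. Leaving out 1 library gave 33 to 402 genes (without DSS PBS replicates 5 and 1). DESeq2 called 355 genes, limma-voom 0 with 1064 at an unadjusted p under 0.05, and a fit of these groups alone 0 with 1270.

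**Figure D4:**
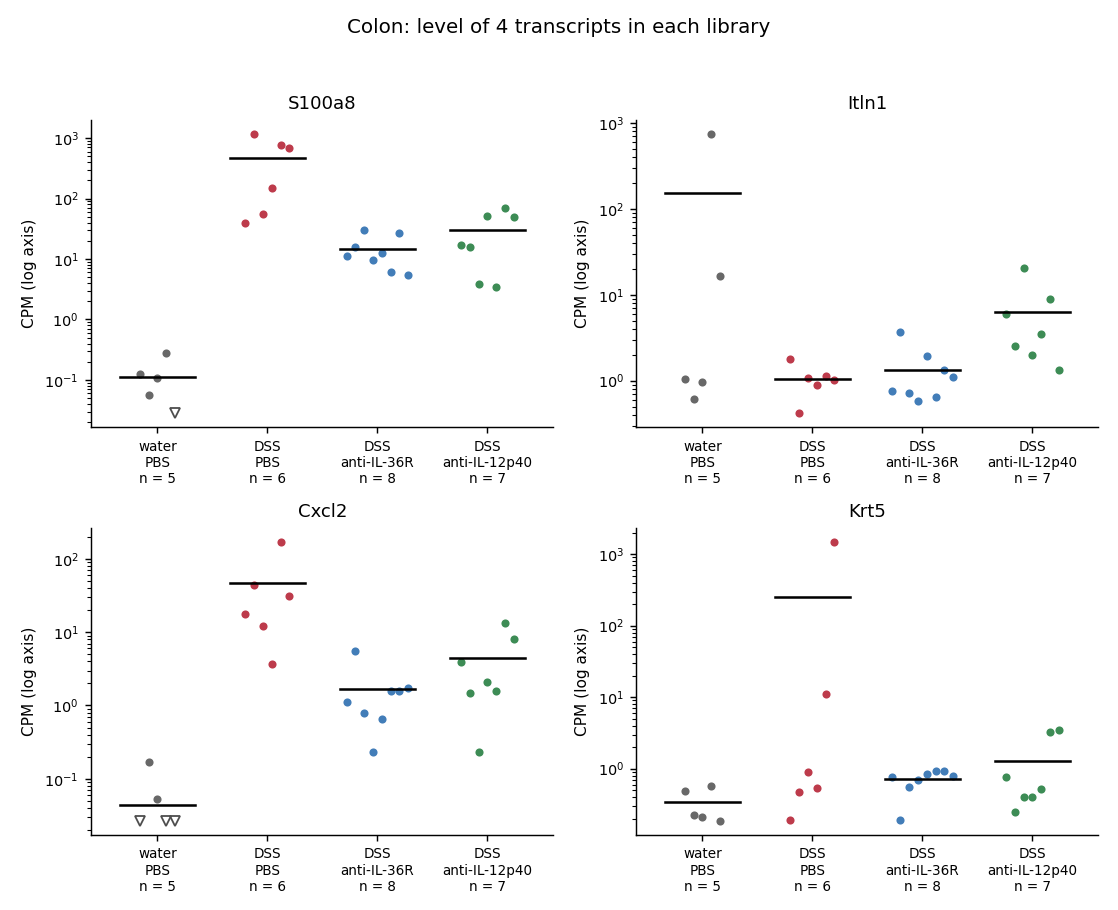
CPM on a log axis (vertical) of S100a8, Itln1, Cxcl2 and Krt5 in each colon library (points), by group; lines are group means and open triangles are libraries with 0 counts, drawn just below the lowest value above 0. Krt5 reaches 1500 CPM in DSS PBS replicate 6, with at most 11.1 CPM in the other 25 libraries, and Itln1 reaches 744 CPM in water replicate 4.

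By edgeR 0 of 15731 genes passed between the antibodies in colon, with 547 at an unadjusted p under 0.05. DESeq2 and limma-voom called 0, and this does not show that the antibodies act alike. Of the 5065 genes that DSS changed, 961 passed in the opposite direction with anti-IL-36R, 814 that rose and then fell and 147 that fell and then rose, against 148.5 and 26.06 for unrelated lists (391 to 1221 and 22 to 413 without 1 library). With anti-IL-12p40 it was 155, 153 that fell after rising and 2 that rose after falling, against 27.21 and 0.293 (33 to 379 and 0 to 16 without 1 library). The sign was opposite for 96.31% and 90.64% of the 5065 genes, against 60.66% and 60.2% in simulations with the same limit. With split PBS libraries the medians were 88.1% and 82.25% (lowest 69.07% and 45.24%). The median counts were 431.5 (1 to 1131) and 65 (0 to 640), and 269 and 0 without the 5 libraries. The antibodies shared 155 genes changed in the same direction, 1 higher and 154 lower, against 0.0226 and 8.336 for unrelated lists, and 0 without the 5 libraries. With split PBS libraries the median was 9.5 (0 to 99), against 1.23 lower for unrelated lists.

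Genes that still differed from water controls in colon numbered 1553 with anti-IL-36R, 1080 higher and 473 lower, and 2706 with anti-IL-12p40, 1701 higher and 1005 lower. The first count was 975 without water replicate 1 and 3972 by limma-voom, and the second was 5028 by limma-voom.

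The difference between skin and colon in the effect of each antibody was tested across 14477 genes measured in both. For anti-IL-36R 793 genes passed, 652 with the more positive change in skin and 141 in colon. The neutrophil gene Stfa2 differed by 9.57 ± 1.79, adjusted p = 0.00164, with -0.72 in skin and -10.30 in colon, and Cstdc5 by 7.03 ± 1.02, adjusted p = 7.55e-05. The serine protease gene Tmprss2 differed by -2.14 ± 0.396, adjusted p = 0.000939. For anti-IL-12p40 243 genes passed, 188 more positive in skin and 55 in colon, but 6 of 100 splits of the libraries called as many (highest other 1275). Sprr2b differed by -3.21 ± 0.478, adjusted p = 0.000106, and Igf2bp3 by 5.94 ± 0.42, adjusted p = 8.16e-14. Without the 5 colon libraries 315 and 67 genes passed. Tissue and chemical cannot be separated in this design, and the calls of Krt5 and Krt6b rested on DSS PBS replicate 6.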

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

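The tests of the splits for IMQ against water and for both differences between tissues, and all tests of anti-IL-36R replicate 7, Igf2bp3 and the squamous transcripts, were chosen after their results were seen.

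In skin, anti-IL-36R replicate 7 lay apart from its group in Il17f (9.02 CPM, others 1.21 to 2.45), Cxcl2 (22 CPM, others 0.171 to 7.44) and Sprr2e (393 CPM, others 64.7 to 161). On a scale from -1 (PBS mean) to 1 (anti-IL-36R mean) with the scored library left out, it scored -0.201, within the PBS range of -1.31 to -0.179, while the other 6 scored 0.00192 to 1.73. Low depth is argued against, with 19.57 M counts against 14.95 M to 18.42 M. A swap with a PBS library stays open, since the highest PBS score of -0.179 lay under the lowest of the other 6 by less than the PBS SD of 0.472. A single wrong label and an animal in which the antibody had no effect cannot be told apart: the score of -0.201 is within the PBS range, but above the PBS mean of -0.79 by more than that SD. Its sample number falls between those of PBS replicates 5 and 6.

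Igf2bp3 was at 40.2 CPM or above in all 7 skin anti-IL-12p40 libraries and at most 1.92 CPM in the other 16. Cells of another tissue would bring many transcripts, but 3 genes separated these libraries upwards (Igf2bp3, 4930463O16Rik and Krt13) and 0 downwards. An effect of the antibody in any tissue is argued against by the colon log2 fold change of -0.0749 ± 0.258, adjusted p = 0.939. Shared reads did not explain it, since Igf2bp1, Igf2bp2 and Igf2bp3 summed to 69 ± 12.1 CPM against 31.3 ± 4.78 CPM with PBS and single counts lay within 0.042% of whole numbers. A batch that follows the sample numbers cannot be told apart from an antibody effect in skin, since the run holds 1 group.

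DSS PBS replicate 6 had Krt5 at 1500 CPM against 0.191 to 11.1 CPM in the other 5, with Krt14 at 1070, Krt13 at 340, Krt6b at 392 and Trp63 at 44.7 CPM. RNA from a skin library is argued against: 50 skin transcripts had a median level of 0.00776 of that set by Krt5, and Krt13 reached at most 1.84 CPM in skin. A DSS response shared by the group at this level is argued against by the other 5, the lowest at 0.191 CPM within the water range of 0.187 to 0.566. A smaller shared rise stays open: without the 5 libraries Krt5 was at 3.01, adjusted p = 0.0284 (0.000414 to 0.178 over the alternatives). Squamous epithelium in the tissue stays open: 4 of 7 basal epidermis genes were highest here (Krt5, Krt14, Col17a1 and Cd34), Trp63 not counted. Sox9 was highest in a water control, so this count cannot decide.

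Of 87 groups tested, 19 had a library far from the rest, against 4.35 expected of unskewed values. IMQ PBS replicate 1 had Flg2 at 123 CPM (others 25.3 to 49.6), Il1rl2 at 29.1 CPM (18.5 to 21.2), Il1f5 at 923 CPM (291 to 464), Sprr2e at 642 CPM (360 to 407), a keratinocyte activation score of 9.32 (8.6 to 8.8) and a cornified barrier score of 8.6 (7.32 to 7.8). IMQ PBS replicate 5 had Cxcl2 at 103 CPM (8.32 to 27.3), and skin anti-IL-12p40 replicate 3 Il17f at 1.02 CPM (0.283 to 0.451). In colon, water replicate 4 had Itln1 at 744 CPM (0.619 to 16.7) and water replicate 3 an interferon gamma score of 3.12 (3.57 to 3.68). Anti-IL-36R replicate 2 had Cxcl2 at 5.6 CPM (0.234 to 1.73) and Itln1 at 3.65 CPM (0.584 to 1.96), and replicate 3 Lcn2 at 20.7 CPM (3.7 to 11.2). DSS PBS replicate 5 had Cxcl2 at 173 CPM (3.71 to 44.7), and anti-IL-12p40 replicate 3 Itln1 at 20.4 CPM (1.33 to 8.88).

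The antibody effects differed between tissues by a tested interaction for 793 genes (anti-IL-36R) and 243 genes (anti-IL-12p40). Differences of log2 fold change, skin minus colon, for anti-IL-36R were Stfa2 9.57, Krt5 8.30, Krt6b 7.83, Cstdc5 7.03, Chil3 5.44, Rnase1 -4.92, Myh2 -3.23, Sprr2k -2.85, Tgm3 -2.40 and Tmprss2 -2.14. For anti-IL-12p40 they were Krt5 7.38, Ltf 6.62, Krt6b 6.37, Igf2bp3 5.94, Stfa2 5.85, Spdef -4.14, Sprr2k -3.28, Sprr2b -3.21, Hs3st1 -2.00, Trim6 -1.79 and Il22 -6.45. Without the 5 colon libraries with squamous, liver or pancreas transcripts, the calls of Krt5, Krt6b, Rnase1, Sprr2k and Tgm3 were lost for anti-IL-36R (1.70, 2.11, 0.507, -2.60 and -1.88), and those of Krt5, Ltf, Krt6b, Sprr2k and Trim6 for anti-IL-12p40 (0.492, 3.90, 0.0373, -2.97 and -1.67). Of 100 splits, the real one included, 1 called as many genes for anti-IL-36R and 6 for anti-IL-12p40 (highest others 717 and 1275). Chance is argued against for anti-IL-36R, though 717 is near 793, and not excluded for anti-IL-12p40. Of the first 41, before the draw was extended, 1 and 2 did, under 5% for both.

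For the comparisons within tissues, that between the antibodies in colon aside, under 5% of the splits drawn called as many genes. Where another split called more than the real one, chance is not excluded. Splits with as many genes as the real one, itself included, numbered 1 of 84 for IMQ (5046 genes, highest other 990) and 1 of 100 for anti-IL-36R (628, highest other 32) and anti-IL-12p40 in skin (1338, highest other 36). Between the antibodies in skin 2 of 100 did (7, highest other 399), and for anti-IL-36R against water 2 of 100 (2003, highest other 2820). The split with 2820 placed the water libraries with anti-IL-36R replicates 2, 4, 5 and 6. Anti-IL-12p40 against water in skin had 1 of 100 (729, highest other 241). In colon it was 1 of 100 for DSS (5065, highest other 2200), 2 for anti-IL-36R (1024, highest other 1207), 4 for anti-IL-12p40 (157, highest other 652), 1 for anti-IL-36R against water (1553, highest other 19) and 1 for anti-IL-12p40 against water (2706, highest other 36). The highest splits of 399, 652 and 1275 genes, several times the real counts, point to a structure of the samples, which was not tested. Between the antibodies in colon the splits decide nothing: the real split called 0 genes by edgeR, with 547 at an unadjusted p under 0.05, so all 100 had to call as many (highest other 2).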

How the results depend on the processing

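The fits without the 5 colon libraries with squamous, liver or pancreas transcripts, with or without water replicate 4 (high Itln1), all alternatives for the comparisons of antibody groups with water, and leaving out libraries for reversal and overlap were chosen after seeing the data. No paired analysis was possible because the labels carry no number that pairs libraries of different groups. For the values that moved, the cause was not tested, except that fits on fewer libraries have less power. Of 222 values of named genes, 188 passed; 97 of these passed under every alternative run and 91 were lost under at least 1. By comparison, 33 of 41 kept their call under IMQ, 0 of 22 with anti-IL-36R and 13 of 33 with anti-IL-12p40 in skin, and 1 of 2 between the antibodies. In colon 35 of 43 did under DSS, 15 of 29 with anti-IL-36R and 0 of 18 with anti-IL-12p40. Over 4158 alternative values, 3748 kept direction and side of the threshold, 385 were weaker, 22 stronger and 3 changed sign. DESeq2 size factors and no filter moved no count of passing genes by more than 1.5 times.

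By DESeq2 the counts were 1112 for anti-IL-36R in skin, 22 between the antibodies in skin, 1305 for anti-IL-12p40 against water in skin, 1558 for anti-IL-36R and 355 for anti-IL-12p40 in colon. By limma-voom they were 2750 and 2677 for anti-IL-36R and anti-IL-12p40 in skin, 453 and 0 in colon, and 3972 and 5028 for the same antibodies against water in colon. Fits of the compared groups alone gave 4 between the antibodies in skin, 1174 and 470 for anti-IL-36R and anti-IL-12p40 against water in skin, 2888 for DSS, and 403 and 0 for anti-IL-36R and anti-IL-12p40 in colon. With PBS replicates 1 to 3 alone, anti-IL-36R and anti-IL-12p40 in skin gave 106 and 429, and with replicates 4 to 6 alone 50 and 193. Without the 5 colon libraries, anti-IL-36R gave 275 (273 shared with all libraries) and anti-IL-12p40 0, and also without water replicate 4 they gave 308 and 0; the differences between tissues were 315 and 67. By fry 33 list calls passed in skin and 45 in colon, and with an estimated correlation 0 and 0.

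Leaving out 1 library gave 2882 to 4992 genes for IMQ (lowest without water replicate 3), 298 to 1186 for anti-IL-36R in skin (without anti-IL-36R replicates 6 and 7), 737 to 1799 for anti-IL-12p40 in skin (without its replicates 1 and 7) and 3 to 8 between the antibodies. Against water it was 698 to 2591 for anti-IL-36R and 118 to 1117 for anti-IL-12p40 in skin, both lowest without water replicate 1, and 975 to 1593 for anti-IL-36R in colon, also lowest without water replicate 1. In colon the ranges were 436 to 1768 for anti-IL-36R (without DSS PBS replicates 6 and 1) and 33 to 402 for anti-IL-12p40 (without DSS PBS replicates 5 and 1).

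Genes reversed numbered 254 to 973 with anti-IL-36R in skin (without its replicates 6 and 7) and 658 to 1480 with anti-IL-12p40 (without its replicates 2 and 7), and 49.5 and 269 as medians over split PBS libraries. In colon they numbered 413 to 1634 with anti-IL-36R and 33 to 394 with anti-IL-12p40, medians 431.5 and 65, and 269 and 0 without the 5 libraries. Genes shared by the antibodies numbered 251 to 827 in skin (without PBS replicate 2 and anti-IL-36R replicate 7), median 25.5, and 33 to 393 in colon, median 9.5, and 0 without the 5 libraries. The colon extremes came without DSS PBS replicate 1 (highest) and replicate 6 or 5 (lowest).

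The sign changed for Krt14 with anti-IL-36R in colon by limma-voom (0.0905), for Krt13 with anti-IL-12p40 in colon without the 5 libraries (0.30) and also without water replicate 4 (0.31), and for the enteric neuron and glia list with anti-IL-12p40 without the 5 libraries (adjusted p = 0.775). In simulated data edgeR recovered 62.7% to 89.6% of genes changed 2-fold, so smaller changes can be missed.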

Other observations

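The list tests were planned, and the transcripts of Igf2bp2 and of other organs were chosen after the data were seen. Antiviral genes passed in colon under DSS and not in skin under IMQ, a difference that was not tested. For type I interferon response genes in skin under IMQ, 24 members were measured, of which 0 passed the test. Here 0 passed when adjusted over the list alone (camera adjusted p = 0.409, and adjusted p = 0.893 with an estimated correlation). In colon under DSS, 24 members were measured, of which 15 rose and 9 were not called. Here 15 rose when adjusted over the list alone (camera adjusted p = 2.07e-05, and adjusted p = 0.486 with an estimated correlation), and 10 rose without the 5 libraries with squamous, liver or pancreas transcripts.

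Between the antibodies in colon no gene passed and 547 had an unadjusted p under 0.05. The camera tests of several lists pointed to lower levels with anti-IL-36R. Fry gave adjusted p of 0.0864 or above for all 34 lists. For B and plasma cell markers, 12 members were measured, of which 0 passed the test. When adjusted over the list alone, 0 passed (camera adjusted p = 1.04e-09, and adjusted p = 0.175 with an estimated correlation). For interferon gamma response genes, 25 members were measured, of which 0 passed the test. Here 0 passed when adjusted over the list alone (camera adjusted p = 9.42e-08, and adjusted p = 0.392 with an estimated correlation). Tests of both list scores gave adjusted p = 0.178 and 0.453.

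Igf2bp2, a relative of Igf2bp3, was at 6.87 ± 1.05 CPM (SD, n = 3) in skin of water controls, 28.6 ± 4.19 (n = 6) under IMQ with PBS, 17.3 ± 6.29 (n = 7) with anti-IL-36R and 12.7 ± 2.61 (n = 7) with anti-IL-12p40.

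Transcripts of liver and pancreas were high in 4 colon libraries. Anti-IL-12p40 replicate 5 had Alb at 884 and Apoa1 at 50.8 CPM, and replicate 2 Amy2a5 at 103, Prss2 at 11.9 and Cpb1 at 10.4 CPM. Anti-IL-36R replicate 3 had Alb at 55.8, Prss2 at 48.1 and Cpb1 at 43.2 CPM, and replicate 8 Cpb1 at 88 and Prss2 at 83.1 CPM. In water controls Alb reached 3.18, Cpb1 0.679 and Prss2 0.0707 CPM.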
